A study of Mus musculus with 3 samples.

How the data were processed

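Neutrophils were sorted by flow cytometry from bone marrow, peripheral blood and lung of female wild-type BALBc/J mice, naive or bearing 4T1 tumours, and labelled with hashtag antibodies, per the labels' protocols. About 24000 cells, 8000 of each hashtagged sample, were loaded into 1 lane of a 10x chip with version 3 chemistry. The deposited gene expression values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 4.0.0, per the file headers, after bcl2fastq 2.20.0.422 and against mm10, per the submitters' processing notes. The deposited hashtag values are counts per barcode for 3 tags and unmapped reads, and the files do not name the tool that counted them. The number of mice is not given. The naive library held 11079 barcodes and 45835269 UMIs, and the 4T1 library 13765 barcodes and 108269052 UMIs, over 32285 genes.

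Each hashtag matrix was joined to the gene expression library whose barcodes carried its tags, which covered 11077 of 11079 naive and 13765 of 13765 4T1 barcodes. Hashtags were assigned with HTODemux of Seurat 5.3.0 in R 4.3.3 at a quantile of 0.99 and seed 1. This gave 10023 singlets, 918 doublets and 138 barcodes without a hashtag in naive, and 12653, 1078 and 34 in 4T1. A ratio rule (5 or more counts and 75% of a cell's tag counts) gave the same tag to 9972 and 12642 cells and another tag to 0 cells. Cells with 200 or more genes and under 10% mitochondrial UMIs were kept, which left 9974 naive and 12646 4T1 singlets. Both libraries were clustered together in scanpy 1.11.5 with leidenalg 0.10.2 under Python 3.11.15, from log values scaled to 10000, 2000 variable genes, 30 components, 15 neighbours and a resolution of 1.0. Clusters with 2 or more markers of 1 other cell type among their 10 leading genes were left out, with haemoglobin genes not counted, a rule set after the data were seen. A kept cluster, mostly of hashtag MHTO3, had 4 haemoglobin genes among its 10 leading genes. The kept cells are called neutrophils from the labels, not from their clusters. Of the 13 kept clusters 11 held over 99% of their cells from 1 library, and no comparison was made within a cluster.

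UMIs were summed over the 9603 naive and 12537 4T1 kept cells and divided by the total to give CPM, with exact Poisson intervals at 95%. Log2 ratios used a prior of 5 CPM, and folds are ratios of CPM without it. For each of 20 gene lists the median log2 ratio over members with 10 CPM or more in either library was taken with its order-statistic interval. Its percentile was taken among 10000 random lists of the same size from 20 bins of expression. The median of all 5385 genes past this floor was subtracted. Shares were given exact Clopper-Pearson intervals. For shares of cells with a UMI each cell was thinned to 1000 UMIs, which left out 295 naive and 175 4T1 cells. The limit that a count of 0 allows is 3 counts of the total. Intervals of list medians cover the spread over member genes, and all other intervals and limits cover counting error only. With 1 library per condition no test was run and no genes were called. The design fixed before the data were examined asked for comparisons within and between tissues, which the unnamed hashtags did not allow, so the libraries were compared as pools of 3 tissues.

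Named genes were, by a rule fixed before the data were examined, the 10 highest and 10 lowest log2 ratios among genes with 100 CPM or more in either library. Mitochondrial, ribosomal protein and haemoglobin genes, immunoglobulin and T cell receptor segments and names given by number alone were left out. The rule added the 2 highest and 2 lowest members of each list and Cd274, Ptgs2, Arg1, Nos2, Pnpla2, S100a8, S100a9, Cxcr2, Cxcr4, Siglecf and Ly6g. Shares of cells were planned for 8 genes. Gapdh, Pkm, Cxcl2, Camp, Sftpc, Pf4 and Hbb-bs, and the mitochondrial genes, were named after their values were seen. Coordinates are 1-based from GENCODE release 21 of the mouse annotation, on mm10, found for 29 of 29 genes looked up.

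Alternatives fixed before the data were examined were TMM scaling (edgeR 4.0.16), median-of-ratios scaling, the mean of the cells' own CPM, all singlets, a prior of 1 CPM, no floor, the ratio rule, 500 genes, 5% mitochondrial UMIs, a resolution of 0.5, each library clustered alone, no thinning, and a floor of 30 CPM for named genes. Others were added after seeing the data. The calculation was tested on simulated counts for all 5385 genes of the comparison of 4T1 with naive, with 200 genes changed. For 50 genes made 2.0-fold higher the median log2 ratio found was 0.91 and the true one 0.91, with 90.0% of the intervals holding the truth. For unchanged genes 95.1% of the intervals held it. The counts were drawn with Poisson error alone, so this checks the calculation and not the spread between samples. Tables were computed with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.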

Results

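Gene expression was measured in single neutrophils sorted from bone marrow, peripheral blood and lung of female wild-type BALBc/J mice. The mice were naive or carried tumours of 4T1, a mammary carcinoma cell line of this strain that spreads to the lung. Each condition was 1 lane of a 10x chip, in which 3 hashtagged samples were pooled, with about 8000 cells loaded per hashtag and 24000 per lane. The deposited naive library held 11079 cell barcodes and 45835269 UMIs, and the 4T1 library held 13765 cell barcodes and 108269052 UMIs. The cells compared were 9603 naive cells with a median of 2280 UMIs and 12537 4T1 cells with a median of 5447 UMIs. They carried a single hashtag, passed the filters and lay outside the clusters led by genes of other cell types. The kept cells held 34985052 naive and 92191352 4T1 UMIs. The hashtags are named MHTO3, MHTO4 and MHTO5 in the naive library and MHTO6, MHTO7 and MHTO8 in the 4T1 library. MHTO4 held 60.2% of the kept naive UMIs and MHTO7 56.9% of the kept 4T1 UMIs. The other hashtags held 17.8% to 23.5% of their library, so values of the libraries weigh MHTO4 and MHTO7 most. No file or label gives the tissues of the hashtags. The planned comparisons within a tissue and between tissues could therefore not be made, and hashtags of the libraries were not paired. With 1 library per condition there were no replicates and no test of any difference. Intervals of genes and shares are 95% intervals of counting error for these libraries, and those of list medians are 95% intervals of the median over member genes.

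The comparison of the 4T1 with the naive library asks how the transcripts of neutrophils differ when mice carry a mammary tumour. The gene with the highest ratio was Wfdc17, a secreted protein of the whey acidic protein family, at 15078 CPM (UMIs scaled to the total of the library) in the 4T1 library and 149 CPM in the naive library. Its level was 101-fold higher (98.3 to 104), and its hashtags lay between 13.4 and 536 CPM in the naive library and between 7969 and 25143 CPM in the 4T1 library. Prok2, a secreted prokineticin that promotes the growth of blood vessels, was 40.2-fold higher in 4T1 (37.98 to 42.7), at 1338 against 33.2 CPM. Ifitm1, an interferon-induced membrane protein, was 27.8-fold higher (27.2 to 28.4), at 6315 against 227 CPM.

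The other 7 genes with the highest ratios include 4 members of 1 family. Saa3, an acute-phase serum amyloid A protein, was 86.3-fold higher in 4T1 (67.7 to 112) but of low level, at 160 against 1.86 CPM. Igfbp6, which binds insulin-like growth factors, was at 325 CPM in 4T1 and 7.23 CPM in naive, a ratio of 45.0 (39.7 to 51.1), and 4T1 cells of other types held 89.8% as many of its UMIs per cell as the kept cells. Upp1, the uridine phosphorylase of pyrimidine salvage, was 9.05-fold higher in 4T1 (8.59 to 9.54). Stfa2, Stfa3, Cstdc5 and Cstdc6 belong to a family of stefin A-like inhibitors of cysteine proteases that lies on chromosome 16. They were 22.0-fold, 14.2-fold, 8.99-fold and 12.1-fold higher in 4T1, with Cstdc5 the most abundant at 7252 against 807 CPM. These genes are near-identical copies, so how the counts divide among them is uncertain. With each hashtag left out in turn, the log2 ratios of these 10 genes, taken with a prior of 5 CPM, lay between 2.52 for Upp1 and 7.74 for Wfdc17, so the folds depend on the hashtags included beyond their counting intervals. Without MHTO4 the folds of Wfdc17, Prok2, Ifitm1, Saa3, Igfbp6, Stfa3 and Cstdc6 were 42.4, 67.9, 12.8, 36.0, 18.9, 45.2 and 21.4. Without MHTO7 those of Wfdc17, Ifitm1, Saa3 and Igfbp6 were 164, 45.9, 188 and 84.02. Those of Wfdc17 and Igfbp6 were 229 and 87.4 without MHTO3, and that of Saa3 was 162 without MHTO5 and 47.6 without MHTO8. Wfdc17 (ENSMUSG00000069792) lies on chromosome 11 from 83703991 to 83706268, Prok2 (ENSMUSG00000030069) on chromosome 6 from 99711299 to 99726392, and Ifitm1 (ENSMUSG00000025491) on chromosome 7 from 140967221 to 140969825 of mm10.

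Among the 10 genes with the lowest ratios, Thbs1 and Cxcr4 were lower in 4T1, and the ratios of most of the others varied with the hashtags included. Thbs1, which encodes the matrix protein thrombospondin 1, was 293-fold higher in naive (214 to 413), at 124 against 0.423 CPM. The naive hashtags held 17.7 to 363 CPM of Thbs1 and the 4T1 hashtags 0.111 to 1.43 CPM, and the fold was 493, 134, 149 and 1092 without MHTO4, MHTO5, MHTO7 and MHTO8. Cxcr4, the chemokine receptor that holds neutrophils in the bone marrow, was 8.16-fold higher in naive (7.91 to 8.41), at 497 against 60.9 CPM. Its hashtags lay between 246 and 1181 CPM in naive and between 30.9 and 135 CPM in 4T1, and its fold was 14.4, 4.99, 4.93 and 13.01 without the same hashtags.

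Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 23.5-fold higher in naive (22.2 to 25.0), at 317 against 13.5 CPM. Hashtag MHTO5 held 1391 CPM of Ptgs2 and the other naive hashtags 33.9 and 8.30 CPM, while the 4T1 hashtags held 0.999, 0.400 and 55.4 CPM. Its log2 ratio of -4.12 was -5.42, -0.05, -3.17 and -5.86 without MHTO4, MHTO5, MHTO7 and MHTO8, each of which leaves 2 hashtags against 3, and its fold was 58.3, 1.05, 10.3 and 572. The following log2 ratios without 1 hashtag are in the same order. The orphan nuclear receptor genes Nr4a3 and Nr4a1, both induced early after stimulation, had ratios of -4.01 (-5.29, -0.16, -3.32 and -4.89) and -3.04 (-4.30, -0.19, -2.09 and -4.66). Bcl2a1b, an antiapoptotic member of a family of near-identical copies, had -3.27 (-4.54, -0.23, -2.40 and -4.57), and Slc7a11, the cystine transporter, -2.91 (-4.17, -0.52, -1.88 and -4.81). Ccl4, a chemokine, had -2.98 (-4.25, 0.54, -2.11 and -3.92), and Dusp2, a phosphatase of MAP kinases, -2.91 (-4.18, 0.44, -1.99 and -4.50). With the mean of the hashtags' log2 CPM, in which the samples weigh equally, these 7 genes lay between -2.84 for Ptgs2 and -1.53 for Ccl4. Ptgs2 (ENSMUSG00000032487) lies on chromosome 1 from 150100031 to 150108227, Thbs1 (ENSMUSG00000040152) on chromosome 2 from 118111876 to 118127133, and Cxcr4 (ENSMUSG00000045382) on chromosome 1 from 128588199 to 128592293.

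With haemoglobin genes left out by rule, the lowest log2 ratio, -5.16 and -5.81 without MHTO4, belonged to Scgb1a1, the secretoglobin of airway club cells, at 192 CPM in naive and 0.499 CPM in 4T1. The surfactant gene Sftpc, a marker of alveolar epithelium, went with it, at 87.8 and 3.07 CPM. Every naive hashtag held both genes, with 118 to 339 CPM of Scgb1a1, and the naive T and B cell-like cells held 157 CPM.

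**Figure D1:**
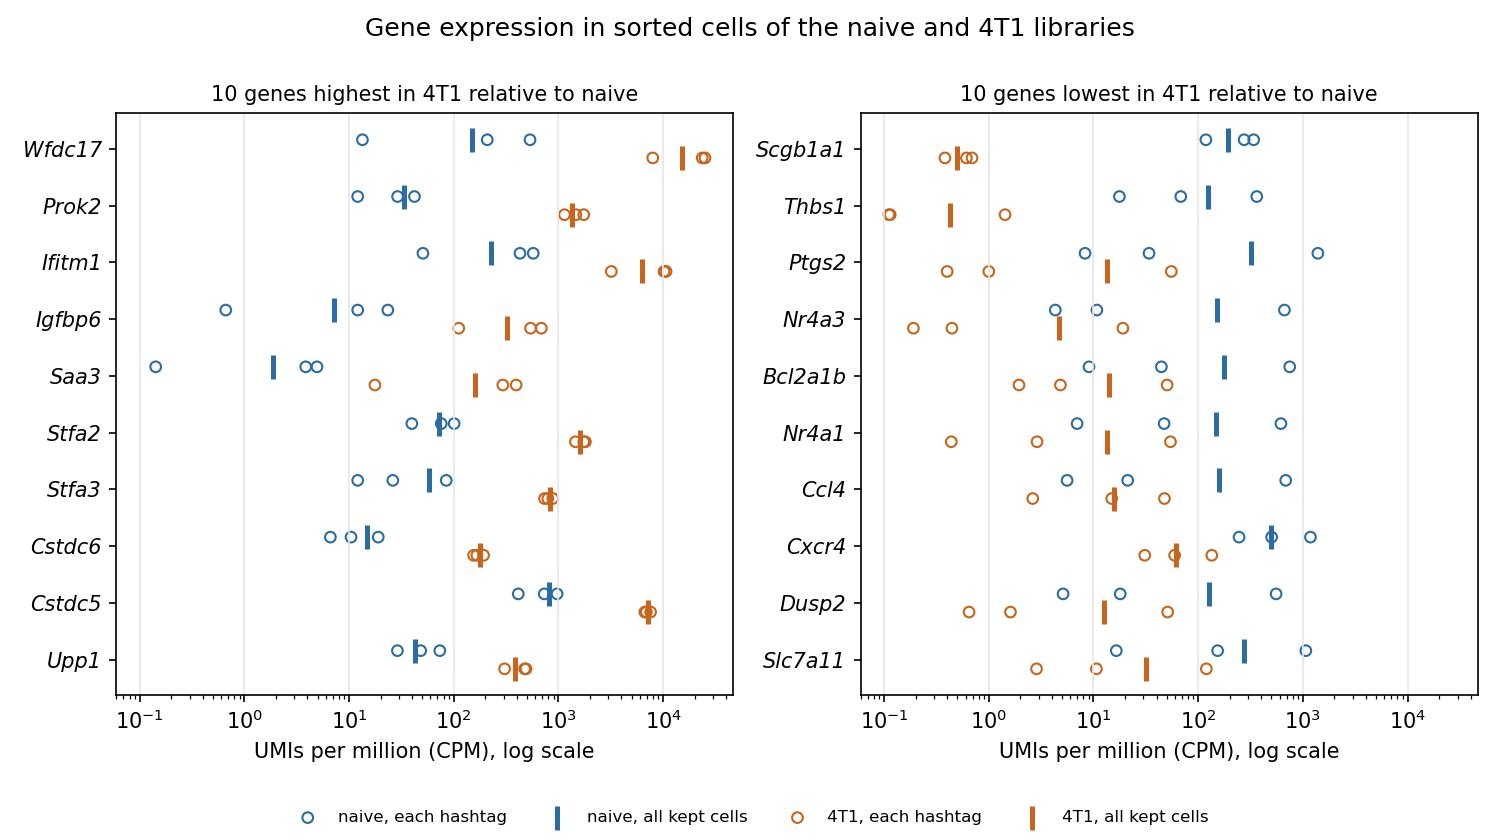
CPM (log scale) of the 10 genes with the highest and the 10 with the lowest log2 ratio, 4T1 over naive, in kept cells. Vertical bars are the libraries and circles the 3 hashtags of each; for Wfdc17 the naive hashtags lie between 13.4 and 536 CPM and the 4T1 hashtags between 7969 and 25143 CPM, while for Ptgs2 the 4T1 hashtag at 55.4 CPM lies above the naive hashtags at 33.9 and 8.30 CPM.

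The genes named for their roles in neutrophils of tumour-bearing mice went in different directions. Nos2, the inducible nitric oxide synthase, was 84.8-fold higher in 4T1 (38.8 to 231) but rare, with 1340 UMIs in 4T1 and 6 UMIs in naive, and the fold lay between 33.7 without MHTO4 and 149 without MHTO7, with 139, 132 and 53.9 without MHTO3, MHTO5 and MHTO8. Arg1, an arginase of suppressive myeloid cells, was not detectable at this depth, with 1 UMI in naive and 0 in 4T1. Cd274, an inhibitory ligand of T cells, was at 45.9 CPM in naive and 8.72 CPM in 4T1, a log2 ratio of -1.89 that was -3.09, -0.39, -1.08 and -2.68 without MHTO4, MHTO5, MHTO7 and MHTO8 and -1.56 with the mean of the hashtags' log2 CPM. The calcium-binding alarmins S100a8 and S100a9 together took 30.2% of naive and 37.0% of 4T1 UMIs, with 16.4% to 38.9% in the naive and 32.6% to 40.3% in the 4T1 hashtags. The log2 ratios of S100a8 and S100a9, both 0.29, were 1.36 and 0.93 without MHTO4, and that of S100a8 was 0.02 without MHTO7. Siglecf, a lectin also found on some neutrophils of tumours, was rare, at 14.5, 1.47 and 10.9 CPM in the naive hashtags and 14.99, 4.78 and 11.2 CPM in the 4T1 hashtags. Its log2 ratio of 0.29 turned to -0.40 without MHTO4, so no direction is given. Pnpla2, the triglyceride lipase of lipid droplets, Cxcr2, the receptor that draws neutrophils out of the marrow, and the sorting antigen gene Ly6g had log2 ratios of -0.32, -0.45 and -0.14. TMM scaling, which shifts the median gene by 0.65, put all 3 above 0, at 0.43, 0.34 and 0.66. Pnpla2 was at 0.23 without MHTO3 and 0.33 without MHTO7, Cxcr2 at 0.16 without MHTO3, and Ly6g at 2.55 without MHTO4, so no direction is given for them.

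Scaling sets the reference for the gene lists. Of the 5385 genes with 10 CPM or more in either library, 21.1% were higher in 4T1 on CPM, 65.2% with TMM and 65.8% with median-of-ratios scaling. The median log2 ratio of all these genes was -0.41 on CPM, and TMM and median-of-ratios scaling shifted it by 0.65 and 0.66. Values of lists are therefore given relative to the median of all genes.

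Genes of glycolysis and hypoxia were high in 4T1 relative to other genes. Their median log2 ratio lay 0.90 above that of all genes (0.15 to 1.10), with 16 of 19 members above it, and above all 10000 random lists matched on expression. The phosphofructokinase gene Pfkl was at 6.40 CPM in naive and 25.1 CPM in 4T1, 3.92-fold higher (3.41 to 4.51). Ldha, which makes lactate from pyruvate, was 2.14-fold higher (2.09 to 2.19), at 594 against 278 CPM, and 3.23-fold higher without MHTO4. Gapdh went with them, at 2593 CPM in 4T1 and 1224 CPM in naive, with a log2 ratio of 1.08 that was 1.98 without MHTO4, and the pyruvate kinase gene Pkm was at 1190 and 736 CPM. Of the 3 members below the median gene, Ndrg1, a gene induced by low oxygen, was the lowest, 5.50-fold higher in naive (5.01 to 6.04) and 8.51-fold without MHTO4. Without any 1 of the 6 hashtags, the list stayed between 0.65 and 0.87 above the median of all genes, and without any 1 of each library between 0.65 and 0.98.

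Genes of inflammatory cytokines and NF-kB, and those of the early response to cAMP, were low in 4T1 relative to other genes with all hashtags in, and varied widely with the hashtags included. The inflammatory list lay at -1.95 relative to all genes (-2.32 to -0.72), with 14 of 16 members below the median gene, and below all 10000 matched random lists. Without MHTO5 it lay at 0.99, and without MHTO4, MHTO7 and MHTO8 at -3.05, -0.93 and -3.07. Leaving out MHTO5 alone takes 1 of 3 samples, of a tissue no label names, from the naive library only. With 1 hashtag of each library left out, the list lay below 0 in 7 of 9 ways, from -4.13 to -0.504, and at 1.07 and 1.97 without MHTO5 and MHTO6 or MHTO7. With the mean of the hashtags' log2 CPM, which is the same however hashtags of the libraries are matched, it lay at -1.34. The chemokine gene Cxcl2 shows the spread, with 9578 CPM in MHTO5, 198 and 65.4 CPM in the other naive hashtags, and 28.2, 10.99 and 1575.5 CPM in the 4T1 hashtags. Ccl3, another chemokine, held 319 CPM in MHTO5, 12.5 and 3.75 CPM in the other naive hashtags, and 0.667 to 14.3 CPM in the 4T1 hashtags. The list for cAMP lay at -1.20 (-2.63 to -0.23), with 11 of 12 members below the median gene. It lay at 0.34 without MHTO5, below 0 in 7 of 9 ways of leaving out 1 hashtag of each library, from -2.88 to -0.81, and at 0.503 and 1.11 in the others, and at -0.93 with the mean of the hashtags' log2 CPM. Without MHTO4, MHTO7 and MHTO8 it lay at -2.17, -0.66 and -1.998. Its member Areg, a growth factor of the epidermal growth factor family, was at 1.03 CPM in naive and at 0.888, 0.248 and 49.0 CPM in the 4T1 hashtags, and its log2 ratio of 1.48 turned to -0.16 without MHTO8 and was 2.41 without MHTO7.

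**Figure D2:**
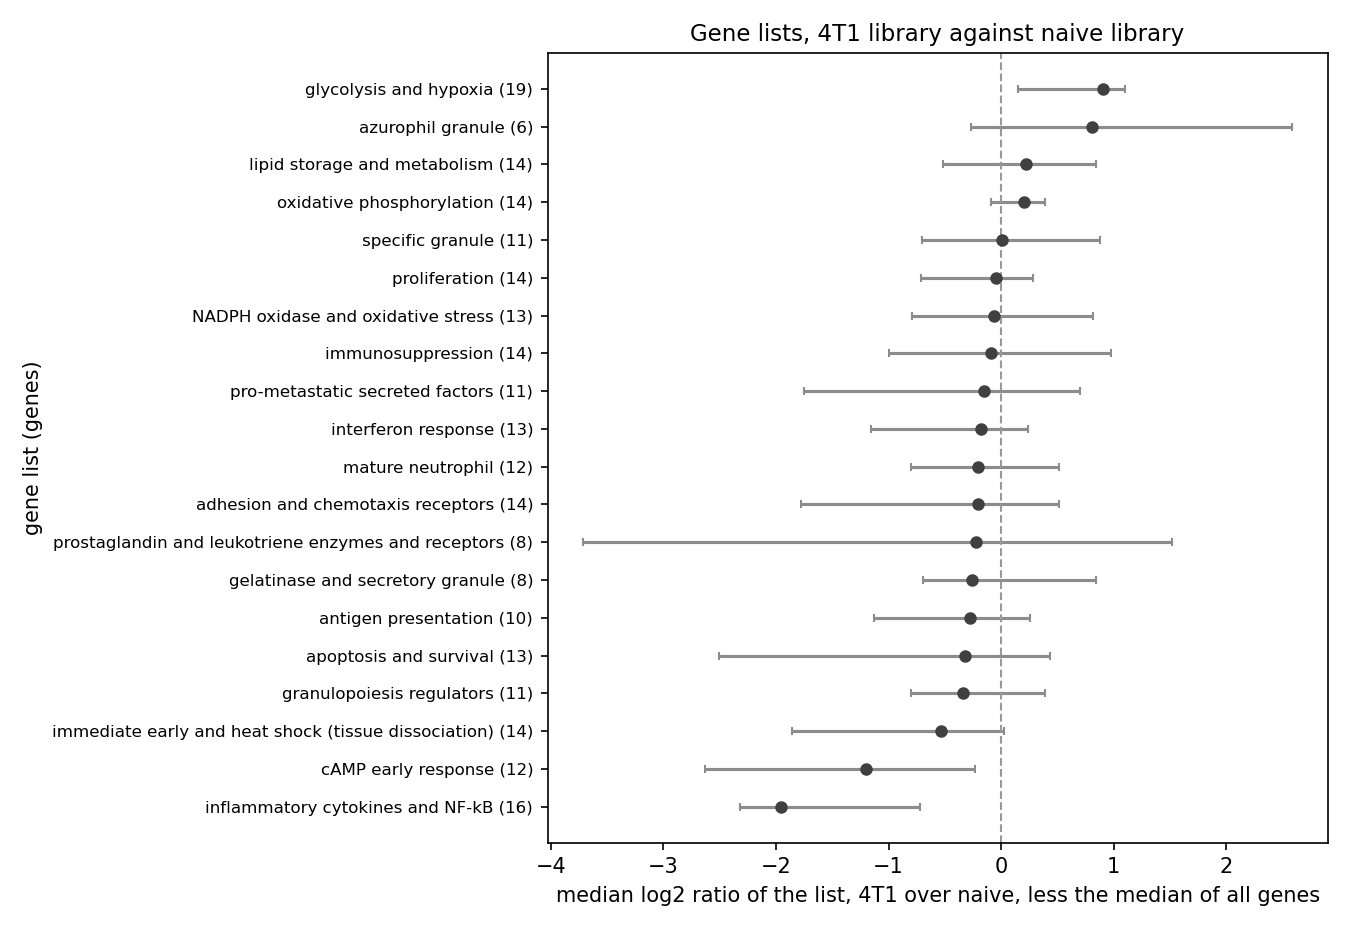
Median log2 ratio, 4T1 over naive, of the members of 20 gene lists less the median of all 5385 genes, with the number of genes measured in brackets and the 95% interval of the median over genes as bars. The glycolysis and hypoxia list lies at 0.90, the inflammatory list at -1.95 and the cAMP list at -1.20.

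The other 17 lists had intervals that included the median of all genes, and several held members that went far apart. In the immunosuppression list, at -0.09, Wfdc17 and Nos2 had the highest ratios, and Olr1, a receptor of oxidised lipoprotein, was 11.7-fold higher in naive (10.2 to 13.5), with 4.98 to 85.9 CPM in the naive and 0.555 to 4.79 CPM in the 4T1 hashtags and a fold of 18.7 without MHTO4 and 5.94 without MHTO5. In the list of lipid storage and metabolism, at 0.22, the fatty acid binding protein gene Fabp5 was 2.98-fold higher in 4T1 (2.80 to 3.18), and 1.70-fold higher without MHTO4, and the lipid droplet gene Plin2 was 1.94-fold higher (1.86 to 2.02). Acsl1, which activates fatty acids, was 3.47-fold higher in naive (3.31 to 3.62). G0s2, an inhibitor of lipolysis, was at 458, 336 and 10036 CPM in the naive and 154, 203 and 1592 CPM in the 4T1 hashtags, and its log2 ratio of -2.25 turned to 0.51 without MHTO5 and was -3.45, -1.40 and -3.68 without MHTO4, MHTO7 and MHTO8. In the interferon response list, at -0.18, Ifitm3 was 3.46-fold higher in 4T1 (3.42 to 3.51) and Rsad2, an antiviral enzyme, 10.3-fold higher in naive (9.61 to 11.04), with 14.8 to 297 CPM in the naive and 4.19 to 24.2 CPM in the 4T1 hashtags. The fold of Rsad2 was 23.9, 5.71, 5.64 and 16.05 without MHTO4, MHTO5, MHTO7 and MHTO8. In the list of pro-metastatic secreted factors, at -0.15, Prok2 and Thbs1 stood at the ends. Gclm, an enzyme of glutathione synthesis in the list of NADPH oxidase and oxidative stress at -0.07, was 4.24-fold higher in 4T1 (4.00 to 4.51), and 7.25-fold higher without MHTO4.

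The azurophil granule list lay at 0.81, above 99.96% of matched random lists, and at 2.10 with the mean of the cells' own CPM. Its interval ran from -0.27 to 2.58 over 6 genes, 5 of them above the median gene. Its member Prtn3, proteinase 3, was at 55.0 CPM in 4T1 and 17.04 CPM in naive, with hashtags between 9.27 and 87.5 CPM in 4T1 and between 2.09 and 24.9 CPM in naive. The log2 ratio of Prtn3, 1.45, was 1.11 with the mean of the hashtags' log2 CPM and 2.56 without MHTO4. It turned to -0.36 without MHTO7, which takes a hashtag from the 4T1 library only, so no direction is given. Ctsc, of the same list, was 6.52-fold higher in 4T1 (5.81 to 7.35). Its hashtags lay between 49.4 and 69.6 CPM in 4T1 and between 5.50 and 15.4 CPM in naive, while those of the other 5 members overlapped. The lists of specific granules, of gelatinase and secretory granules and of mature neutrophils lay at 0.00, -0.26 and -0.20, and that of specific granules at 0.82 with the mean of the hashtags' log2 CPM. Camp, the cathelicidin of specific granules, ranged from 1795 to 28943 CPM among the naive and from 1332 to 13665 CPM among the 4T1 hashtags. The specific granule list took 6.43% of naive UMIs (6.42% to 6.43%) and 4.70% of 4T1 UMIs (4.70% to 4.71%), with 1.10% to 9.89% among the naive and 1.79% to 6.80% among the 4T1 hashtags. It was 1.18% of naive UMIs without MHTO4 and 1.92% of 4T1 UMIs without MHTO7, so no direction is given. Granulopoiesis regulators lay at -0.34, proliferation at -0.05 and oxidative phosphorylation at 0.20. Immediate early and heat shock genes, the list of tissue dissociation, lay at -0.53, above only 0.13% of matched random lists. They took 0.801%, 0.101% and 1.56% of UMIs in the naive and 0.375%, 0.116% and 0.423% in the 4T1 hashtags. Adhesion and chemotaxis receptors lay at -0.21, antigen presentation at -0.28, apoptosis and survival at -0.32, and prostaglandin and leukotriene genes at -0.22.

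Shares of cells with a UMI of a gene were compared after thinning every cell to 1000 UMIs, with T and B cell-like cells of each library as the background from free RNA. These were 147 naive cells with a median of 4098 UMIs and 78 4T1 cells with a median of 3329 UMIs. Ptgs2 was found in 21.2% of naive cells (20.4% to 22.1%) and 2.35% of 4T1 cells (2.09% to 2.63%). Its background was 8.16% in naive and 0 of 78 cells in 4T1, which allows up to 3.85%. Only hashtag MHTO5, at 61.3%, exceeded the share in naive T and B cell-like cells. The other naive hashtags lay below that share, at 2.77% and 1.17%, or 1.96% together, so it is not all free RNA shared by the droplets. Of the 84 naive T cell-like cells, 72 carried MHTO5. In 4T1, hashtag MHTO8 held Ptgs2 in 7.61% of cells, above the 3.85% that its background allows, and the others in 0.180% and 0.0210%. Il1b, an inflammatory cytokine, was found in 72.7% of naive and 66.5% of 4T1 cells over backgrounds of 27.2% and 17.9%, and hashtag MHTO4 lay below the naive background at 24.3%. Without MHTO5 the naive share of Il1b was 60.1%, below that of 4T1. Isg15, an interferon-induced ubiquitin-like protein, was found in 36.4% and 21.1% over 5.44% and 3.85%, and Ltf, the lactoferrin of specific granules, in 35.3% and 29.6% over 14.97% and 14.1%. Without MHTO5 the naive share of Isg15 was 18.1%, and without MHTO4 that of Ltf was 20.5%, both below the 4T1 shares. These leave-outs, and that for Il1b, take a hashtag from the naive library only. The hashtags held Isg15 in 31.2%, 5.17% and 74.6% of naive and 18.3%, 6.53% and 42.8% of 4T1 cells. They held Ltf in 21.5%, 63.9% and 19.6% of naive and 15.7%, 51.5% and 16.2% of 4T1 cells. No direction is given for these 3 genes. Cd274 was found in 5.90% of naive and 1.53% of 4T1 cells over backgrounds of 2.72% and 1.28%, whose intervals held both shares, while hashtag MHTO5 held it in 13.3%. Siglecf was found in 1.02% and 1.45% over backgrounds of 0.680% (0.0172% to 3.73%) and 0 of 78 cells, which allows up to 3.85%. So few background cells cannot show whether Siglecf lay above background. Before thinning it was found in 2.48%, 0.932% and 2.54% of cells in MHTO3, MHTO4 and MHTO5, uneven within 1 lane. Mki67, a marker of dividing cells, was found in 0.612% and 0.299%, below the 2.04% and 3.85% of T and B cell-like cells, which can divide. Arg1 was found in 1 naive cell and in 0 of 12362 4T1 cells, which allows a share of up to 0.0243%. Its share of 4.76% in naive T and B cell-like cells was higher, so they give no background for it.

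**Figure D3:**
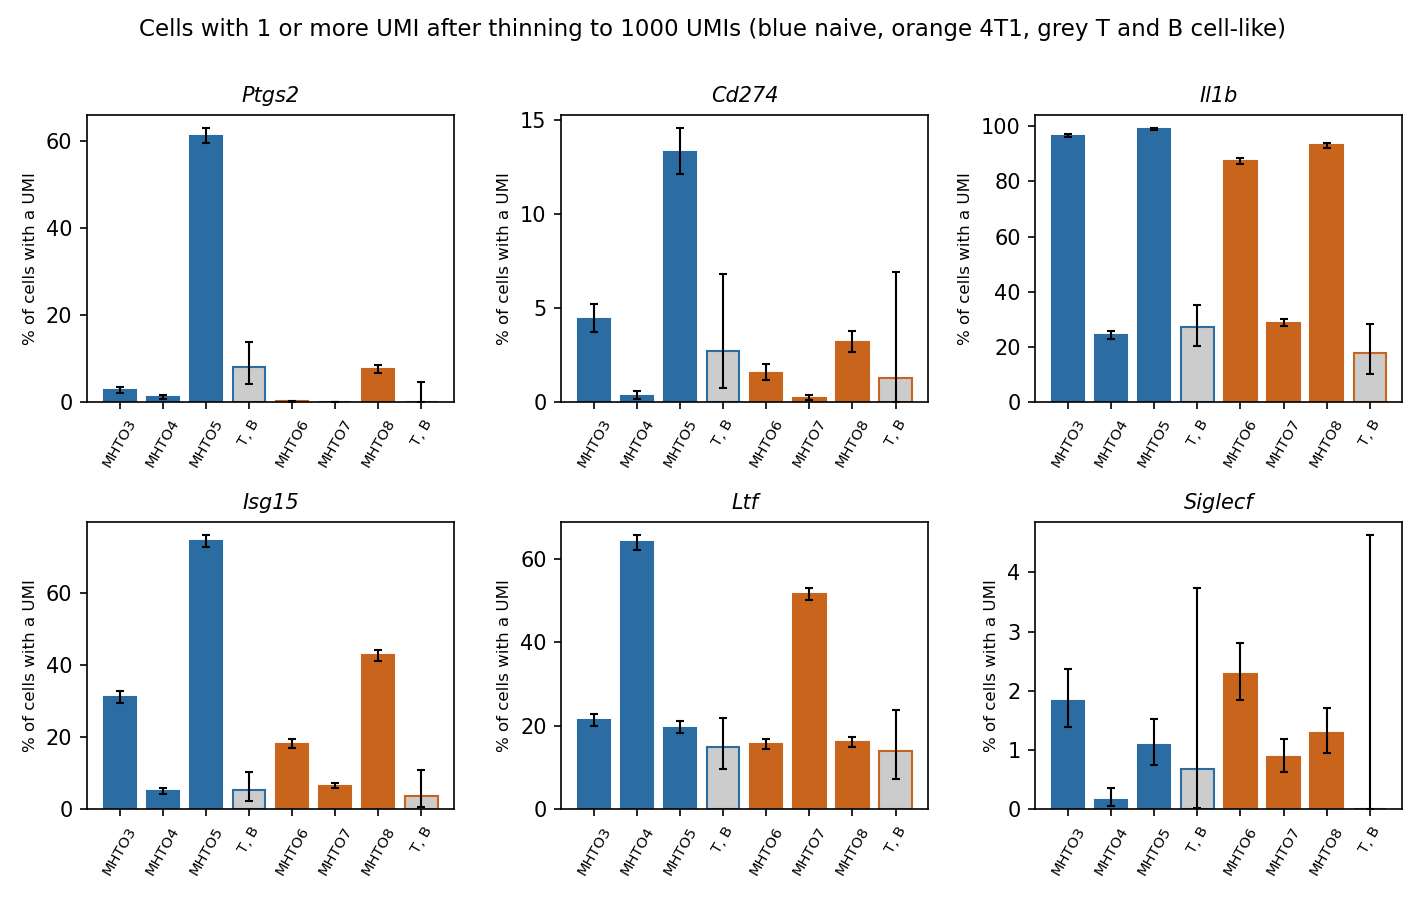
Percent of cells with 1 or more UMI of 6 genes after thinning to 1000 UMIs, per hashtag and, in grey, in T and B cell-like cells of each library, with exact 95% binomial intervals. Ptgs2 reaches 61.3% in MHTO5 and at most 7.61% in the 4T1 hashtags, while Il1b lies between 24.3% and 98.9% in the naive and between 28.7% and 93.1% in the 4T1 hashtags.

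The sort left few cells of other types. Clusters led by their genes held 3.72% of naive cells (3.36% to 4.11%) and 0.862% of 4T1 cells (0.708% to 1.04%) and were left out. A cluster with Scgb1a1, Sftpc, Sftpa1, Ccl21a, Epas1 and Ramp2 among its leading genes held 91 cells in naive, 90 of them in MHTO5, and 4 in 4T1. Its markers of endothelial cells, fibroblasts and epithelial cells had medians of 759, 169 and 137 CPM, so it held markers of several types. T cell-like cells numbered 84 and 66, dendritic cell-like cells with genes of macrophages 80 and 27, and B cell-like cells 63 and 12. In the T cell-like cluster the markers of T cells, NK cells, and basophils and mast cells had medians of 388, 240 and 44.3 CPM. In the dendritic cell-like cluster those of monocytes and macrophages had a median of 419 CPM and those of dendritic cells 183 CPM. A cluster led by Pf4, a platelet chemokine gene, held 53 naive cells, 49 of them in MHTO3, and 0 of 12646 4T1 cells, which allows up to 0.0237%. Its neutrophil markers had a median of 1043 CPM and its megakaryocyte and platelet markers 62.7 CPM, so its cells are not shown to be of another type. With each library clustered alone, the cluster led by Pf4 held 120 naive cells, 77 of them in MHTO5 and 41 in MHTO3. In the kept cells Pf4 was at 38.1 CPM in MHTO5 and 7.56 CPM in MHTO3. Haemoglobin genes were among the leading genes of a kept naive cluster of 3230 cells, 3020 of them in MHTO3. The haemoglobin gene Hbb-bs was at 1093, 214 and 9.76 CPM in the kept cells of MHTO3, MHTO4 and MHTO5, and at 4.19 CPM in the 4T1 library.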

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

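The share on shared barcodes given here was computed after the result was seen. Barcode sequences of each library's cells also had counts in the hashtag matrix of the other library, with its 3 tags. No comparison used these counts. They made up 0.233% of the named hashtag counts on naive cell barcodes, 15818 counts, and 1.14% on 4T1 cell barcodes, 52676 counts, above the 3 counts that a count of 0 allows. The 60 barcodes that occur in both libraries carried 77.8% of them in naive and 84.9% in 4T1. No explanation was tested.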

How the results depend on the processing

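Alternatives were fixed before the data were examined, except equal weight per hashtag, cells with under 2% of UMIs from Ltf, Camp and Ngp (low-granule cells), removal of the top 5% of Scrublet scores, a correction for exon length, the mean of the hashtags' log2 CPM, and leaving out each hashtag or 1 of each library, which were chosen after seeing the data. Removal of Scrublet's own calls was not run as planned, since its threshold marked 498 naive and 0 4T1 cells. Of the list medians under these alternatives 308 stayed within their intervals, 11 moved and 6 turned, and of the values of genes given a direction or named by rule 339, 456 and 22 did. With all hashtags in, the inflammatory list lay between -2.27 and -1.34, the cAMP list between -1.56 and -0.93 and the glycolysis list between 0.55 and 1.01. Without MHTO5 the inflammatory list turned to 0.99, the cAMP list to 0.34, Ccl4 to 0.54, Dusp2 to 0.44 and G0s2 to 0.51. Without MHTO5 and with MHTO6 or MHTO7 left out as well, the inflammatory list turned to 1.07 and 1.97 and the cAMP list to 0.503 and 1.11, and with MHTO8 left out as well the inflammatory list moved to -0.504. Without MHTO4 or MHTO8 the inflammatory list moved to -3.05 and -3.07, and without both to -4.13, where the cAMP list moved to -2.88. Without MHTO3 and MHTO8, and without MHTO4 and MHTO6, the inflammatory list moved to -3.33 and -2.83. Siglecf turned to -0.40 without MHTO4, Prtn3 to -0.36 without MHTO7 and Areg to -0.16 without MHTO8. Pnpla2 turned to 0.43 with TMM and 0.44 with median-of-ratios scaling, and to 0.23 without MHTO3 and 0.33 without MHTO7. Cxcr2 turned to 0.34 and 0.36 with these scalings and to 0.16 without MHTO3. Ly6g turned to 0.66 and 0.67 with these scalings, 0.045 with the mean of the cells' own CPM, 0.21 with equal weight per hashtag, 0.92 with the mean of the hashtags' log2 CPM, 0.78 in low-granule cells, and 2.55, 0.0077 and 0.093 without MHTO4, MHTO6 and MHTO8. The scalings shift the median gene by 0.65 and 0.66, more than these 3 genes' ratios. In low-granule cells the specific granule list moved to 0.997 and the proliferation list to -0.78. Oxidative phosphorylation moved to 0.44 with the mean of the cells' own CPM and to -0.15 with no floor, where the reference is the median of 18511 genes. The kept share moved to 97.4% of naive and 99.3% of 4T1 cells under 5% mitochondrial UMIs, and to 95.6% of naive cells with each library clustered alone. Apart from the scalings and the floor, the cause was not tested. Of the 20 named highest and lowest genes, 13 to 20 were shared under the other settings that kept all hashtags, and 14 with a floor of 30 CPM. Depth differed between the libraries, so unthinned shares of Siglecf were 1.98% in naive and 5.37% in 4T1, against 1.02% and 1.45% after thinning. No paired analysis was possible because each condition had 1 library and no label pairs the hashtags.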

Other observations

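All tests in this part were chosen after the results were seen. Genes of the mitochondrial genome went different ways. The cytochrome oxidase gene mt-Co1 held 495 to 1341 CPM in the naive and 3008 to 3464 CPM in the 4T1 hashtags, and mt-Co2 474 to 878 CPM and 1361 to 1479 CPM. The complex I gene mt-Nd3 was 2.08-fold higher in naive, at 41.2 against 19.9 CPM, and 1.19-fold without MHTO4. Without MHTO4 the fold of mt-Co1 in 4T1 went from 3.08 to 5.53. The median mitochondrial share of a cell was 0.265% in naive and 0.766% in 4T1. Markers of other cell types in the kept cells were uneven among the hashtags. The list of basophils and mast cells was at 4.50, 63.6 and 4.94 CPM in the naive hashtags and at 0.380 CPM in 4T1, and the naive value of 40.2 CPM was 4.75 CPM without MHTO4. The erythroid list was at 593 CPM in naive, 313 CPM without MHTO3, and at 9.02 CPM in 4T1, 0.277 CPM without MHTO7. The epithelial list was at 297 CPM in naive, 470 CPM without MHTO4, and at 6.63 CPM in 4T1, 10.6 CPM without MHTO7. The neutrophil list summed to 369315 CPM in naive, 189354 CPM without MHTO4, and 426994 CPM in 4T1.

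Longer genes had lower ratios of 4T1 to naive. Over 5 bins of 5382 genes by exon length, the median log2 ratio was -0.16, -0.22, -0.40, -0.54 and -0.75, at median lengths from 1599 to 10402 bases. Across genes, which are not independent, Spearman's rho was -0.37 for exon length and -0.29 for the whole gene, the 2 measures computed. Less the median of each gene's bin of exon length, the inflammatory list lay at -2.18, the cAMP list at -1.02 and the glycolysis list at 0.68.

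Of 1061 genes with 100 CPM or more in either library, 72 were higher and 183 lower in all 3 4T1 hashtags than in all 3 naive hashtags. Together these are 24.0% of the genes. The counts are on CPM, on which 21.1% of the 5385 genes were higher in 4T1, against 65.2% with TMM scaling. The excess of lower over higher genes therefore depends on the scaling. A gene without ties is separated by 1 of the 10 splits of the hashtags into 3 and 3, so the mean over splits is 10% by construction. It is not a chance rate for samples of different tissues. The 10 genes with the highest ratios, picked from these same values, were among the 72 higher ones, and Thbs1, Cxcr4 and Scgb1a1 among the 183 lower. 2 of the 10 splits of the 6 hashtags separated as many genes, the real one with 255 included, and the highest other split separated 289. So few splits cannot give a share under 0.05.

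UMIs of epithelial and haemoglobin genes occurred in kept naive cells, although the cells were sorted as neutrophils. RNA of epithelial cells shared by the droplets of the lane is a candidate source of Scgb1a1 and Sftpc, since their ratio was 2.32, 2.12 and 2.15 in the 3 naive hashtags, highest over lowest 1.10, and 2.13 in T and B cell-like cells. Each hashtag held 0.645 to 0.775 UMIs of Scgb1a1 per cell, and the mixed cluster led by Scgb1a1 had a ratio of 2.72. Haemoglobin RNA shared by all droplets is argued against, since Hbb-bs was at 2.08, 1.40 and 0.0241 UMIs per cell in MHTO3, MHTO4 and MHTO5, highest over lowest 86.2. Haemoglobin RNA carried within each sample stays open, and no biological explanation was tested.

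For the 10 genes with the highest ratios, free RNA of the 4T1 lane is argued against as the whole source. Cells of other types in that library held a median of 11.1% of the kept cells' UMIs per cell of these genes. Saa3, at 22.6%, and Igfbp6, at 89.8%, were the highest, and the argument does not cover Igfbp6. A different share of granule-rich cells is also argued against as the whole source. In low-granule cells the median log2 ratio of the 10 genes was 95.4% of that in all kept cells. The filter did not hold stage fixed, since the specific granule list lay at 0.997 relative to all genes in low-granule cells. A different mix of stages among low-granule cells therefore stays open. A difference between the lanes cannot be told apart from the tumour, since each condition had 1 library. The tumour's effect on neutrophils stays open beside it, as an untested explanation.

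For the low inflammatory list in 4T1, it stays open whether 1 of the 3 naive hashtagged samples sets it. Without MHTO5 the list lay at 0.99 relative to all genes, against -2.28 and -3.05 without MHTO3 and MHTO4. With MHTO6, MHTO7 or MHTO8 left out beside MHTO5 it lay at 1.07, 1.97 and -0.504. In the other 6 ways of leaving out 1 of each library it lay below 0. All values above 0 were thus without MHTO5 and with MHTO8 kept in. MHTO5 and MHTO8 held most T cell-like cells of their libraries, 72 of 84 and 52 of 66, but no label pairs them. The lowest, middle and highest hashtags of each library, set against each other for each gene, gave -0.49, -0.80 and -1.98, and the mean of the hashtags' log2 CPM gave -1.34, all under 0, but ranks do not show which samples share a tissue. Stress during tissue handling stays open, since 11 immediate early genes of the list of tissue dissociation had a median of -1.09 and ranged from -2.37 to 1.20, while its 3 heat shock genes had a median of -0.20 and ranged from -0.52 to 0.20. The tissue of the samples, which no label gives, and the tumour also stay open.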
